A study of Saccharomyces cerevisiae with 167 samples.

How the data were processed

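The series holds 167 arrays in dual colour, and 13029 probes are on each array. The deposited values are log2 ratios of the Cy5 channel to the Cy3 channel of 1 array, per the labels and the values. The base was read from the values: for ratios under 0.5, raising 2 to the deposited value gave whole thousandths in 100% of cases within 0.02 of a thousandth, whereas base e gave 6.0% and base 10 3.5%. The normalization that the authors applied, the scanner, the background correction and the spot filtering are not given in the sources used here, so whether the authors scaled or centred the arrays stays unknown, while the direction of each ratio is given by the dyes in the labels. Stressed, immunoprecipitated or mutant material was in Cy5 on the arrays used, and no array had the dyes exchanged. Medians of the deposited arrays lay between -0.14 and 0.26. Arrays carry no read depth, so their number limits the precision.

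H4 on the chromatin arrays was Myc-tagged H4 taken with an anti-Myc antibody, Snf2 was Myc-tagged as well, and the genomic DNA reference was sonicated DNA. In the time courses the T codes of the chromatin arrays (T0 to T900) carry no unit in the labels, whereas the expression labels give seconds. Time course expression used poly(A) RNA against control RNA of unstressed wild-type cells for both strains, and the other expression arrays used total RNA. The H4 references were wild-type genomic DNA throughout, and those of acetylated H4 were wild-type genomic DNA except for sets 2 and 3 of the deletion strain, which used DNA of the deletion strain per the labels. The SNF2 ORF probe was at -2.33 and -2.76 in these 2 sets and at -1.54 in set 1 (wild type -1.10, -1.24 and -0.46). This argues against the labelled reference, since the probe should not lie below wild type where both channels lack SNF2. Only this probe was checked. At T900 in the deletion, repeats 2-a and 2-b of H4 set 2 (r = 0.91 across probes) were averaged to 1 value.

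Each array was centred on the median of all its probes. Probes were kept with a value on at least 2 arrays of each group, or 1 where a group had 1 array, and 10 probes had no value on at least 1 array. Expression was tested on ORF probes alone (6269, of which 5777 were matched by name to the annotation of the assembly R64), and chromatin on all probes. Intergenic probes are named after an ORF. Of 5811 such probes 5801 were placed between 2 genes of that annotation, 2816 at the promoter side of 1 gene, 1471 between divergent genes and 1514 at no promoter, and the 4111 distinct promoter probes used served 5359 genes. The placement was checked on 4511 probes, whose values had r = 0.61 with the ORF they are named after, 0.21 with the gene to the left and 0.61 with that to the right. Names were taken from the annotation and no coordinates are printed, since the arrays give none.

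Direct comparisons (both states on 1 array) were tested against 0, and comparisons of groups by the difference of their means, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, and Benjamini-Hochberg adjusted p under 0.05 over all probes tested as the threshold. In the time courses 1 mean was fitted per strain and time, and the spread was shared over all arrays of that course, so that times with 1 array were assumed to vary like the rest. Strain differences in the response were tested as interaction contrasts, by F over 6 contrasts for chromatin and at 900 s for expression. Values given for tests over all times are means of the differences from T0. The groups and numbers of arrays, the tests, the 30 gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. By that rule the text could name, per comparison, the 5 largest rises and the 5 largest falls past the threshold with the same direction on every array or with groups that did not overlap. It could also name the 4 members of a described list with the largest change, the fixed genes HSP12, HSP26, HSP42, HSP78, HSP82, HSP104, SSA3, SSA4, CTT1, TPS1, RPL3, RPS3 and ACT1, and the deleted genes. An intergenic probe between divergent genes is named with both.

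Gene lists were tested with camera of limma with the preset correlation of 0.01, and again with an estimated correlation, on lists of at least 5 measured members, and expression used ORF probes and chromatin the promoter probe of each gene. On the single deletion arrays the list medians were set against 10000 random lists. Promoters of genes called in expression were summarised per array as their median minus that of all other promoter probes, with an exact permutation test over arrays where there were 2 groups. Relations across genes are Spearman correlations, and genes are not independent replicates. In the expression comparison after heat shock limma estimated an infinite prior, so that a single spread served all genes.

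The alternatives were: values without centring, arrays scaled to 1 median absolute deviation, robust eBayes, probes complete on every array and each replicate left out in turn. Others were set numbers as a replicate block, the difference of the ratios to genomic DNA in place of the direct ratios, an estimated list correlation, genes with at least a 2-fold change, ORF probes in place of promoter probes and promoters that serve 1 gene. Chosen after seeing the data were centring on the ORF probes, the print batch of the Snf2 arrays as a block, set 1 alone for acetylated H4, strain differences with 1 value per set (deletion minus wild type, mean over the times that both strains have), and H4 in stationary phase without ribosomal DNA, mitochondrial probes and ORFs beside the ribosomal DNA. The print batches are groups of Snf2 arrays with 9 or 2 probes without a value. Their name is an assumption, since no label used here gives a batch. Set numbers paired the strains of the time courses (r between 0.58 and 0.80 across probes for H4 and 0.34 and 0.75 for acetylated H4) and, weakly, the Snf2 arrays (0.11 to 0.19).

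The fits were tested on simulated data, in which changes of known size were added to random noise with the residual spread of each probe. At a log2 change of 1 limma recovered 34.7% of 75 planted changes in the heat shock expression comparison, 96.0% for H4 after heat shock and 46.7% for the Snf2 change. The first value does not describe the real heat shock expression test, which used a single spread for all genes. That test called SSA3 at 0.51, whereas 0% of simulated changes of 0.5 were recovered. It recovered 73.3% for the wild-type H4 time course at T900, 26.7% for H4 strain by time and 0% for the expression difference between strains at 900 s, where a change of 2 was also recovered in 0%. Camera called 1 of 100 lists without a change and 20 of 20 lists shifted by 0.5. Values were handled with the R package data.table, version 1.17.8, and with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Every array was used.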

Results

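The series followed budding yeast (Saccharomyces cerevisiae) through heat shock and into stationary phase, the state that cultures enter when nutrients run out. It set gene expression beside the occupancy and the acetylation of histone H4 before and after each stress. The binding of Snf2, the ATPase of the SWI/SNF chromatin remodelling complex, was measured before and after heat shock. The 167 dual-colour arrays carried 13029 probes each, of which 6269 were for open reading frames (ORFs) and 4111 were the intergenic probes used for the promoters of genes. H4 and Snf2 were Myc-tagged and were taken from formaldehyde cross-linked chromatin with an anti-Myc antibody. Acetylated H4 was taken with an antibody against the acetylated histone, except that the description of the 3 direct stationary-phase arrays of acetylated H4 names an anti-Myc antibody. Heat-shocked cells were hybridised directly against unstressed cells on 3 arrays each for expression, H4 and acetylated H4 (39°C against 30°C for H4 and acetylated H4, per the labels), and stationary cells against log-phase cells on 3 arrays each for the same measurements. A further 3 arrays per state set H4 against genomic DNA, 3 set acetylated H4 against genomic DNA, and 3 set acetylated H4 against H4. Snf2 chromatin was set against input chromatin on 3 arrays from unstressed cells and 5 arrays after heat shock. Time courses of heat shock in wild-type and snf2 deletion cells gave 39 H4 values per probe and 39 of acetylated H4, with 2 or 3 values per strain and time code, and 13 arrays of expression. Another 13 expression arrays held 1 array per comparison of single deletion strains. Array medians as deposited lay between -0.14 and 0.26 on the log2 scale. The number of arrays limits the precision of every value, and the p-values measure the spread between arrays, since the labels do not say that the arrays of a group came from separate cultures.

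Heat shock of wild-type cells raised the mRNA of molecular chaperones and stress proteins and lowered that of ribosomal proteins. The aldehyde dehydrogenase genes ALD3 and ALD2 rose 29.6-fold (log2 change 4.89 ± 0.09, SD, n = 3) and 27.8-fold (4.80 ± 0.27). The Hsp90 co-chaperone gene CPR6 rose 20.8-fold (4.38 ± 0.36), and HSP12, which encodes a small membrane-associated heat shock protein, rose 16.8-fold (4.07 ± 0.02). YBR116C, an ORF of unknown function, rose by 4.45 ± 0.33. The small heat shock gene HSP26 rose by 3.61 ± 0.42, the catalase gene CTT1 by 3.57 ± 0.18, and the Hsp90 gene HSP82 by 3.46 ± 0.14. The Hsp70 gene SSA4 rose by 3.37 ± 0.51, and HSP78, HSP42 and HSP104 by 2.81 ± 0.31, 2.74 ± 0.32 and 2.74 ± 0.39. TPS1, which makes trehalose 6-phosphate, rose by 2.55 ± 0.31. Large falls past the threshold included those of RPL2A (-3.42 ± 0.42), RPS9B (-3.23 ± 0.52), RPS0B (-3.22 ± 0.30) and RPS0A (-3.21 ± 0.40), all ribosomal protein genes, and RPL3 fell by 2.73 ± 0.26. ACT1, the actin gene, was at -0.13 ± 0.47 and RPS3 at -0.41 ± 0.13, and neither passed the threshold. Each of these directions was shared by 3 of 3 arrays for the genes that passed.

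Among the gene lists fixed in advance, 29 of 30 chaperone genes rose on heat shock (29 adjusted over the list alone), with a list median of 2.79, BTN2 at 3.89 and the co-chaperone gene STI1 at 3.76 (adjusted p = 0.414 with an estimated correlation). Of 30 general stress genes, targets of the transcription factors Msn2 and Msn4, 26 rose and 1 fell, the same counts adjusted over the list alone, with DDR2 at 3.90 (adjusted p = 0.414 with an estimated correlation). Of 137 ribosomal protein genes 132 fell and 1 rose (134 and 2 adjusted over the list alone), with a median of -2.40 (adjusted p = 0.414 with an estimated correlation). Ribosome biogenesis genes fell in 57 of 71 cases (59 adjusted over the list alone), among them NOP56 (-2.87), NSR1 (-2.48) and GAR1 (-2.16), whose products act in the nucleolus (adjusted p = 0.414 with an estimated correlation). Translation factors fell in 16 of 25 cases, TEF4 by 2.63 and YEF3 by 2.34, with 17 falls and 1 rise adjusted over the list alone (adjusted p = 0.596 with an estimated correlation). Subunits of RNA polymerases I and III fell in 13 of 20 cases, the same count adjusted over the list alone, with RPA49 at -1.80 (adjusted p = 0.414 with an estimated correlation). Oxidative phosphorylation genes rose in 25 of 35 cases and fell in 1 (26 and 1 adjusted over the list alone), with CYC7 at 2.28 and QCR10 at 1.80 (adjusted p = 0.625 with an estimated correlation). In amino acid biosynthesis 25 of 52 genes fell and 5 rose (26 and 5 adjusted over the list alone), with ARO4 at -2.63 and the arginine gene ARG3 at 1.93 (adjusted p = 0.601 with an estimated correlation). Of the 30 lists 11 passed camera with the preset correlation and 0 with an estimated one. Over all ORF probes 2164 passed the limma threshold, 1038 higher and 1126 lower after heat shock, of which 373 and 437 changed at least 2-fold. Without replicate 1 the count was 1311. In this comparison a single spread was estimated for all genes, so the SD of each gene is given in place of its p.

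Stationary-phase cells, compared with log-phase cells, had more mRNA of 23 of 30 general stress genes and less of 128 of 137 ribosomal protein genes. MET2, which acts in methionine synthesis, rose 27.6-fold (log2 change 4.79 ± 0.36, SD, n = 3, adjusted p = 1.04e-06). The old yellow enzyme gene OYE3 (4.70 ± 0.21), the drug exporter gene ATR1 (4.53 ± 0.16), the sporulation gene SPS100 (4.47 ± 0.20) and DDR2 (4.38 ± 0.53) followed. HSP26 rose by 3.90 ± 0.84, HSP12 by 2.22 ± 0.13, CTT1 by 2.13 ± 0.12, HSP42 by 2.04 ± 0.47, TPS1 by 1.15 ± 0.34 and SSA4 by 0.81 ± 0.21. HSP104 was at -0.16 (adjusted p = 0.462), HSP82 at 0.20 (adjusted p = 0.438) and ACT1 at 0.05 (adjusted p = 0.826). The largest falls past the threshold were the cell wall mannoprotein gene CWP1 (-4.37 ± 0.24), ASC1 (-3.74 ± 0.16), and the ribosomal protein genes RPS22A (-3.03 ± 0.04), RPL9B (-3.03 ± 0.03) and RPL6A (-3.01 ± 0.17). Directions were shared by 3 of 3 arrays for each gene that passed. The limma test called 2211 ORF probes, 1102 higher and 1109 lower, and 1284 without replicate 1.

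Of 137 ribosomal protein genes 128 fell in stationary phase (129 adjusted over the list alone), with a median of -2.21 (adjusted p = 0.459 with an estimated correlation). General stress genes rose in 23 of 30 cases, 23 adjusted over the list alone, including GRE1 at 4.27 and YRO2 at 2.96 (adjusted p = 0.480 with an estimated correlation). Of 30 chaperone genes 15 rose and 2 fell (15 and 3 adjusted over the list alone), with a median of 0.41 and SSE2 at 2.02 (adjusted p = 0.672 with an estimated correlation). Amino acid biosynthesis genes rose in 20 of 52 cases and fell in 5, the same counts adjusted over the list alone, with MET10 at 3.57, ARG1 at 3.20 and ARG3 at 2.89 (adjusted p = 0.613 with an estimated correlation). The pheromone response list rose in 14 of 20 cases, 14 adjusted over the list alone, with the agglutinin gene AGA1 at 3.07 and the cell fusion gene FUS1 at 2.40 (adjusted p = 0.613 with an estimated correlation). Genes of the M/G1 transition rose in 9 of 12 cases, 9 adjusted over the list alone, among them the daughter-cell genes DSE4 (1.95) and DSE1 (1.67) and the chitinase gene CTS1 (1.62), with adjusted p = 0.480 with an estimated correlation. Camera passed 13 of the 30 lists in stationary phase with the preset correlation and 0 with an estimated one. Under both stresses 495 genes rose, against 182.5 expected by chance, and 628 fell, against 199.2 expected. Opposite directions were seen for 43 and 59 genes. Across genes, which are not independent replicates, the heat shock and stationary changes had a Spearman correlation of 0.53.

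Histone H4 was lost from heat shock genes after heat shock, over ORFs as well as promoters. On the 3 arrays that set heat-shocked against unstressed chromatin, H4 fell at the ORF of BTN2, which encodes a v-SNARE binding protein induced by heat (-2.32 ± 0.23, SD, n = 3, adjusted p = 6.67e-05). It also fell at the ORFs of HSP82 (-2.26 ± 0.13, adjusted p = 4.92e-05), HSP104 (-2.13 ± 0.28) and HSC82 (-2.08 ± 0.29), and at the HSP104 promoter (-2.18 ± 0.35, adjusted p = 0.000128). The HSP12 promoter, which shares its probe with YFL015C, fell by 2.07 ± 0.11 (adjusted p = 4.92e-05), the SSA4 promoter by 1.93 ± 0.20 and the HSP78 promoter by 1.57 ± 0.16. H4 fell in the region between HSP82 and YAR1 by 1.44 ± 0.06 and in that between PDC6 and CTT1 by 1.11 ± 0.04. The HSP26 promoter fell by 1.10 ± 0.32 (0.04 through genomic DNA) and the HSP42 promoter by 0.76 ± 0.16. The promoters of ACT1 (-0.08, adjusted p = 0.362) and RPL3 (0.07, adjusted p = 0.448) did not pass, nor did the HSP26 ORF (-0.18, adjusted p = 0.484). Rises were smaller: the ribosomal protein gene RPL28 rose by 1.00 ± 0.13, the ORF IRC13 by 0.99 ± 0.15, and the prefoldin gene GIM3 by 0.85 ± 0.31 (but -0.55 through genomic DNA). The mating pheromone gene MF(ALPHA)1 rose by 0.80 ± 0.23 and the RPL3 ORF by 0.63 ± 0.09. Each direction was shared by 3 of 3 arrays.

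Among chaperone promoters, H4 fell at 28 of 29 (28 adjusted over the list alone), with a median of -1.09 and the region between TAD2 and KAR2 at -1.75 (adjusted p = 0.639 with an estimated correlation). General stress promoters fell in 17 of 23 cases (19 adjusted over the list alone), with a median of -0.53 and TFS1 at -0.94 (adjusted p = 0.639 with an estimated correlation). At 124 ribosomal protein promoters H4 rose in 39 and fell in 3 (47 and 5 adjusted over the list alone), with a median of 0.14 and the RPS19A promoter at 0.60 (adjusted p = 0.823 with an estimated correlation). Relative to all other promoter probes, the H4 change was lower at the 760 promoter probes of genes whose mRNA rose (mean of the array medians -0.10 ± 0.03, SD, n = 3) and higher at the 879 of genes whose mRNA fell (0.06 ± 0.01). Over all probes 2808 passed, 1308 higher and 1500 lower, and at least 2-fold changes were nearly all losses (73 lower, 1 higher). Without replicates 1, 2 and 3 in turn the count was 1262, 961 and 4310, and without centring the split was 2074 higher and 1185 lower.

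**Figure D1:**
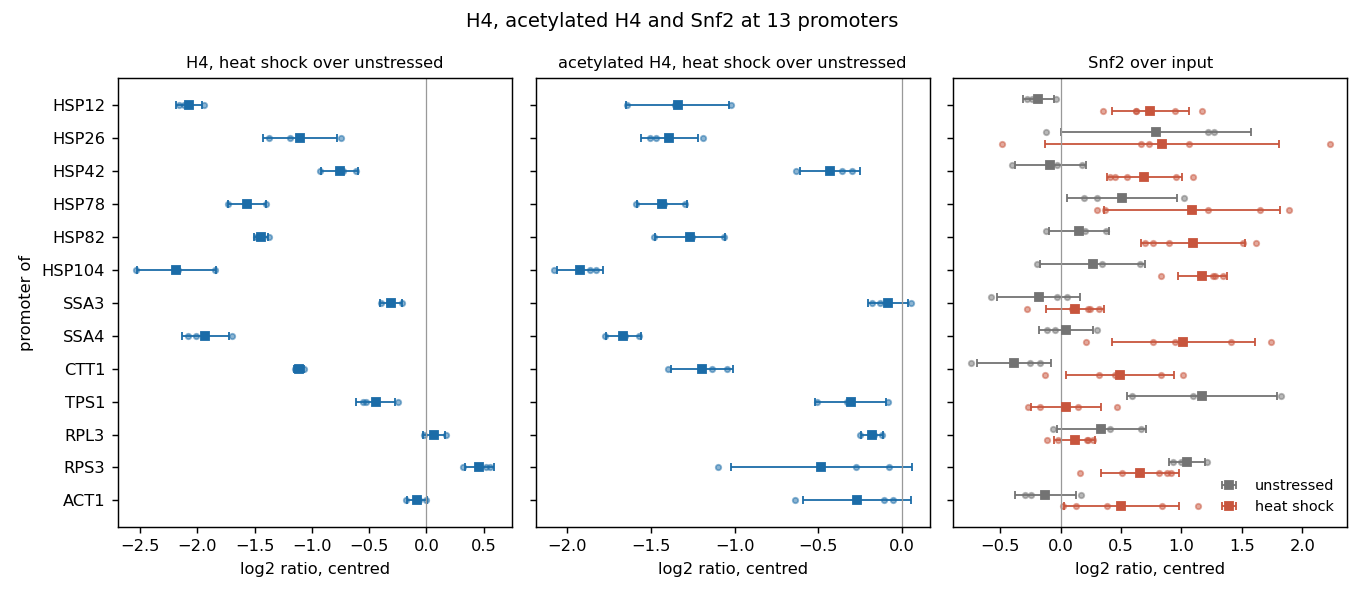
Promoter probes of 13 genes named in advance: log2 ratio of H4 (left) and of acetylated H4 (centre) in heat-shocked over unstressed cells, 3 arrays each, and of Snf2 over input (right) in unstressed cells (3 arrays) and after heat shock (5 arrays), with points for arrays, squares for means and bars for the SD. The HSP104, HSP12 and SSA4 promoters had the lowest H4 means, at -2.18, -2.07 and -1.93, while ACT1 (-0.08) and RPL3 (0.07) stayed near 0.

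Acetylated H4 fell at the same kind of promoter after heat shock. The signal at the promoter of HSP30, a plasma membrane heat shock protein, fell by 2.29 ± 0.37 (SD, n = 3, adjusted p = 0.000195) and its ORF by 2.15 ± 0.16, next to the ORF YCR022C (-1.94 ± 0.13). The HSP104 promoter was at -1.92 ± 0.14 (adjusted p = 0.000118), SSA4 at -1.67 ± 0.10, HSP78 at -1.43 ± 0.15, HSP26 at -1.39 ± 0.17 and HSP12 at -1.34 ± 0.31. The largest rises were at an intergenic probe beside YIL170W (1.39 ± 0.13), the YOL155W-A promoter (1.35 ± 0.18) and the mannosyltransferase gene OCH1 (1.11 ± 0.19). The ACT1 promoter was at -0.27 (adjusted p = 0.157). Chaperone promoters fell in 22 of 29 cases and rose in 1, counts that held adjusted over the list alone, with APJ1 at -1.79 and a median of -0.86 (adjusted p = 0.231 with an estimated correlation). Ribosome biogenesis promoters fell in 50 of 66 cases (56 adjusted over the list alone), among them NOG2 (-1.44) and RPF1 (-1.29), with adjusted p = 0.231 with an estimated correlation. Ribosomal protein promoters fell in 55 of 124 cases and rose in 1, with 62 falls adjusted over the list alone and a median of -0.28 (adjusted p = 0.518 with an estimated correlation). At promoters of genes whose mRNA fell the mean relative to all other promoters was -0.19 ± 0.02, and at those whose mRNA rose 0.05 ± 0.03 (SD, n = 3), which turned to -0.09 for genes that rose at least 2-fold. The test called 3454 probes, 1614 higher and 1840 lower, and 1997 without replicate 1.

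The same heat shock question was also asked by way of genomic DNA and by the ratio of acetylated H4 to H4, in 3 against 3 arrays. Against genomic DNA, H4 fell at the ORFs of HSP82 (-2.14, SE 0.15, adjusted p = 0.000555), BTN2 (-2.01, adjusted p = 0.00377) and HSP104 (-1.57, adjusted p = 0.0231) and at the SSA4 promoter (-1.33, adjusted p = 0.0237). It rose at the ribosomal protein genes RPS23A (1.09, SE 0.16), RPL28 (0.97) and RPL3 (0.94, adjusted p = 0.0231). The HSP12 and HSP104 promoters, at -1.33 (adjusted p = 0.0921) and -1.15 (adjusted p = 0.0715), did not pass. Acetylated H4 against genomic DNA fell at HSP30 (-2.46, SE 0.16, adjusted p = 2.66e-05), BTN2 (-2.02) and the HSP104 promoter (-1.86), and rose at NUP85 (1.35), which encodes a nuclear pore subunit, and at OCH1 (1.18). The ratio of acetylated H4 to H4 rose at SIS1 (1.00, SE 0.15), an Hsp40 co-chaperone gene. It fell at HSP30 (-1.10), at the promoter of RRB1 (-1.12), at NSA2 (-0.95) and RPL36B (-1.05), which serve ribosome assembly or the ribosome, and at ARO4 (-1.08). Each of these had adjusted p = 0.0382, with every array of 1 state above every array of the other. Over 124 ribosomal protein promoters its median was -0.33, where limma called 0 over all probes and 44 falls adjusted over the list alone (adjusted p = 0.102 with an estimated correlation). Over 29 chaperone promoters it was 0.07 (adjusted p = 0.469 with an estimated correlation). At promoters of induced genes this ratio, relative to all other promoters, had a difference of 0.10 and at repressed ones of -0.15, each with an exact permutation p of 0.1 over 20 splits, two-sided, the smallest that 3 arrays against 3 allow. The difference at induced genes was smaller for genes that rose at least 2-fold and reversed over their ORF probes. The tests called 40 probes for H4 (9 higher, 31 lower), 643 for acetylated H4 (224 higher, 419 lower) and 8 for the ratio (1 higher, 7 lower). The H4 count was 361, 0 and 2 without replicates 1, 2 and 3 in turn. The acetylated H4 count was 50 without replicate 1 and 134 without replicate 2, and the ratio gave 0 without any of the replicates, while scaling the arrays turned the H4 split to 92 higher and 58 lower.

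In stationary phase, H4 was higher over the ribosomal DNA and did not pass the threshold at the promoters of HSP12, HSP104 and SSA4. The ribosomal DNA probe RDN37-1 rose by 2.65 ± 0.37 (SD, n = 3, adjusted p = 0.00696), the intergenic probe iRDN5-1 by 2.75 ± 0.46 and the mitochondrial intron probe IntQ0185A by 3.13 ± 0.49. Over 13 ribosomal DNA probes the median was 2.22, with all 13 higher, and over 60 mitochondrial probes it was -0.16, with 3 higher and 2 lower. Most mitochondrial probes thus did not share the rise of IntQ0185A, and whether its signal is H4 was not tested. Through genomic DNA the ribosomal DNA median was 1.96, with 0 probes called. The mitochondrial carnitine carrier gene CRC1 (-1.43 ± 0.46), the translocon gene SSS1 (-1.19 ± 0.36) and the cholinephosphotransferase gene CPT1 (-1.11 ± 0.38) fell, whereas the differences of their ratios to genomic DNA were 0.15, 0.13 and 0.24. The HSP12, HSP104 and SSA4 promoters were at -0.13, -0.07 and 0.01 (adjusted p = 0.621, 0.764 and 0.968). Among 124 ribosomal protein promoters H4 rose at 11 (41 adjusted over the list alone), with RPL21A at 0.85, RPL2A at 0.79 and a median of 0.23 (adjusted p = 0.983 with an estimated correlation). The test called 386 probes, 303 higher and 83 lower, of which 238 were left without ribosomal DNA, mitochondrial probes and ORFs beside the ribosomal DNA. The count was 0 without replicate 1 and 22 without replicate 2.

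Acetylated H4 in the direct stationary-phase arrays, whose description names the anti-Myc antibody, was higher at the HSP12 promoter (0.82 ± 0.18, SD, n = 3, adjusted p = 0.0174) and ORF (0.81 ± 0.07). It was also higher at the promoters of ACT1 (0.80 ± 0.29, adjusted p = 0.0247), RPL3 (0.82 ± 0.33, adjusted p = 0.0274) and RPS3, shared with RHO5 (0.98 ± 0.32, adjusted p = 0.0188). The HSP26 promoter fell by 0.56 ± 0.26 (adjusted p = 0.0491). The largest falls were at LEU9 (-2.35 ± 0.88), SFL1 (-2.23 ± 1.00), RPT5 (-2.17 ± 1.36), DPB2 (-2.16 ± 1.20) and the centromere probe CEN4 (-2.13 ± 0.70), which through genomic DNA were at 0.80, 0.61, 0.52, 0.55 and 0.20. The sign was the same through genomic DNA at 67.3% of the 2685 called probes and at 45.7% of the 890 of them that changed at least 2-fold. There limma called 0 probes for acetylated H4 (2342 at unadjusted p under 0.05) and 0 for H4 (1469 at unadjusted p under 0.05). The ratio of acetylated H4 to H4 rose at the divergent promoters of GLY1 and IES6 (1.59, SE 0.25) and of EPL1 and BUD27 (1.47, SE 0.14), at the HSP12 ORF (0.81, adjusted p = 0.0471) and at the promoter of PDC6 and CTT1 (0.72, adjusted p = 0.0493). It fell at YPR123C (-2.37, SE 0.28), YOR131C (-2.34) and the promoter of TPS1 and MEO1 (-1.56, adjusted p = 0.0384). The 152 ORF probes that fell at least 2-fold in this ratio had a median of -1.42, and the 256 intergenic probes beside them one of 0.08. Of 23 general stress promoters 6 rose in this ratio (13 rises and 1 fall adjusted over the list alone), with a median of 0.66 (adjusted p = 0.963 with an estimated correlation). Directly, 2685 probes were called for acetylated H4 (1109 higher, 1576 lower), with 1340, 1023 and 678 without replicates 1, 2 and 3 in turn. The ratio gave 640 calls (297 higher, 343 lower), 0 without any of the replicates and 0 with the arrays scaled.

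Snf2 was above input at most chaperone promoters after heat shock. In unstressed cells it was above input at the ORFs YOR142W-A (1.97 ± 0.27, SD, n = 3, adjusted p = 0.00738), YPR177C (1.93 ± 0.16) and UBP2 (1.87 ± 0.14), a ubiquitin protease gene. It was also above input at the promoters of RPS21A (1.52, adjusted p = 0.0173), RPL19B with YBL028C (1.52, adjusted p = 0.0372) and TPS1 with MEO1 (1.17, adjusted p = 0.0399). It was below input at the aquaporin-like ORF AQY3 (-0.92 ± 0.28). The 294 ORF probes at least 2-fold above input before heat shock had a median of 1.37, and the 384 intergenic probes beside them one of 0.15, so signal at such ORFs was mostly not shared by their neighbours. YOR142W-A, YPR177C and UBP2 (YOR124C) all carry names in YOR or YPR. ORF probes so named were also frequent among the falls of acetylated H4 on the direct stationary-phase arrays. Whether these ORF probes report Snf2 binding was not tested. After heat shock Snf2 was above input at the promoters of HSP104 (1.17 ± 0.20, SD, n = 5, adjusted p = 0.000541), HSP82 with YAR1 (1.10 ± 0.43, adjusted p = 0.00404) and SSA4 (1.02 ± 0.59, adjusted p = 0.0111). The promoters of HSP12 (0.74 ± 0.32, adjusted p = 0.00801) and HSP42 (0.69 ± 0.31, adjusted p = 0.00947) were above input too, while HSP26 (0.84 ± 0.97, adjusted p = 0.0720) did not pass. The highest values were at subtelomeric probes, YDR544C (2.11 ± 0.28, adjusted p = 0.000115), YHR217C (1.99 ± 0.32) and TEL9L (1.83 ± 0.24). After heat shock 27 of 29 chaperone promoters were above input (28 adjusted over the list alone), with CPR6 at 1.25 and FES1 at 1.18 (adjusted p = 0.545 with an estimated correlation). Of 124 ribosomal protein promoters 42 were above and 1 below (64 and 1 adjusted over the list alone), with adjusted p = 0.579 with an estimated correlation. Glycolytic promoters were above input in 9 of 16 cases (11 adjusted over the list alone), with ADH1 at 1.35 and TDH3 at 1.10 (adjusted p = 0.545 with an estimated correlation). Of 298 promoters whose genes rose at least 2-fold, Snf2 was called at 2.0% before and 33.2% after heat shock, against 3.4% and 12.5% of the other promoters. At 365 promoters whose genes fell at least 2-fold it was called at 3.3% and 15.1%. The number of arrays differed, and calls over all probes went from 673 to 3107.

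Set directly against each other, the 5 heat shock and 3 unstressed Snf2 arrays differed past the threshold at 8 probes, all higher after heat shock. These included the divergent promoter of TAD2 and the Hsp70 gene KAR2 (1.48, SE 0.20, adjusted p = 0.0446), the iron-sulfur gene ISA1 (1.44, SE 0.20) and the glucokinase gene GLK1 (1.32, SE 0.15, adjusted p = 0.0389). The HSP82 with YAR1, HSP12 and HSP104 promoters were at 0.95, 0.93 and 0.91 (adjusted p = 0.139, 0.0990 and 0.119). Of 29 chaperone promoters 1 rose (21 adjusted over the list alone), with a median of 0.72 (adjusted p = 0.503 with an estimated correlation). Promoters of induced genes, relative to all others, had a higher Snf2 median after heat shock (0.15 ± 0.04, n = 5) than before (-0.05 ± 0.05, n = 3), with an exact permutation p of 0.0179, two-sided over 56 splits. With exchanges within the print batches only it was 0.0333 over 30 splits, the smallest they can give, and the 3 pairs of equal set number differed by 0.13, 0.22 and 0.26. At promoters of repressed genes the difference was -0.11. The counts were 673 probes before (669 above input, 4 below), 3107 after (1878 above, 1229 below) and 8 for the change. The first was 0 without replicate 1 and 2896 without replicate 3. The second was 1704, 1218 and 1301 without replicates 2, 3 and 4 in turn, and the change gave 0 without any of the replicate numbers. With set numbers as a replicate block, by which 2 of 3 sets paired best, limma called 0 for the change, with 2083 at unadjusted p under 0.05 in the unblocked test. The groups of arrays told apart by their missing probes, taken as print batches, gave 2 as a block and 0 in the larger group alone.

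During the heat shock time course H4 left the HSP12 promoter in wild-type cells. Its log2 ratio to genomic DNA went from 0.35 ± 0.41 (SD, n = 2) at T0 to -1.76 ± 0.18 (n = 3) at T300 and -1.77 ± 0.60 (n = 3) at T900. The change to T900 was -2.12 (SE 0.25, adjusted p = 3.15e-05). In the snf2 deletion it went from 0.27 ± 0.09 (n = 2) to -0.18 ± 0.10 at T300 and -0.64 ± 0.13 at T900 (change of -0.91, adjusted p = 0.606). The difference between these changes was 1.20 (SE 0.36, unadjusted p = 0.00207 in limma, adjusted p = 1.0), and for all times together the unadjusted p was 0.000252 (adjusted p = 0.821). The HSP104 promoter was at -1.50 ± 0.47 in wild type and -1.34 ± 0.35 in the deletion at T300, and the SSA4 promoter at -1.53 ± 0.43 and -1.21 ± 0.15. Their differences between the strains in the change to T900 had the opposite sign to that of HSP12, at -0.43 (unadjusted p = 0.430 in limma) and -0.66 (unadjusted p = 0.195). H4 also fell in wild type at the HSP12 ORF (-1.66, adjusted p = 0.0107) and the FMP45 promoter (-1.27, adjusted p = 0.0287). In tests over all times it fell at BTN2, HSP42 and the HSP12 promoter (means over times of -1.48, -1.13 and -1.07). In the deletion the test over all times called HSP42 (mean -0.86, adjusted p = 0.00263), YAP6 and an intergenic probe beside YML100W. Across all times H4 was higher in the deletion at the promoters of the glycolytic gene TDH3 (0.86, SE 0.08, adjusted p = 4.04e-08), the cell wall gene SED1 (0.98, SE 0.17, adjusted p = 0.000704) and HSP12 (0.59, SE 0.09, adjusted p = 0.000106), and at the HSP42 ORF (0.74). The deleted gene SNF2 itself had less signal (-1.77, SE 0.15). These tests take the arrays as independent, although the times of 1 set are repeated measures. With 1 value per set and 3 sets the adjusted p was 0.0228 for TDH3, 0.0154 for HSP12, 0.00626 for HSP42 and 0.00879 for SNF2, and SED1 did not pass (0.0688). General stress promoters had higher H4 in the deletion in 7 of 23 cases (14 and 1 lower adjusted over the list alone), with adjusted p = 0.0671 with an estimated correlation. Trehalose and glycogen promoters were higher in 5 of 15 (8 adjusted over the list alone), with adjusted p = 5.39e-05 with an estimated correlation. Both list tests also take the arrays as independent and were not repeated with 1 value per set.

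The H4 strain difference was called at 306 probes, 276 higher and 30 lower in the deletion, and at 570 (470 higher, 100 lower) with the set numbers, which pair the strains, as a replicate block. With 1 value per set it was 117 (115 higher, 2 lower). Over promoters of heat-induced genes that rose at least 2-fold, H4 lay higher in the deletion by 0.06, 0.03 and 0.06 in sets 1, 2 and 3, and at 7 of 7 time codes. Exchanging the strains of whole sets gave an exact p of 0.25, the smallest that 8 exchanges allow. Of the 276 probes 174 were above input for Snf2 after heat shock, against 39.8 expected, and 30 before it, against 14.2 expected. In the direct heat shock arrays 136 of them lost H4, against 31.8 expected. The wild-type T900 test called 7 probes, all lower (20 with the block), and the deletion's limma test called 0 (798 at unadjusted p under 0.05, 11 with the block). The limma test for a strain difference in the time response called 0 (119 at unadjusted p under 0.05). The strain count was 86 without replicate 2 and 141 without replicate 3, its split without centring was 214 higher and 70 lower, and the wild-type T900 count was 2 without replicate 1 and 0 without replicate 3. The tests over all times called 45 probes in wild type (131 with the block) and 3 in the deletion (35 with the block). They gave 3, 7 and 15 in wild type without replicates 1, 2 and 3, and 6 and 0 in the deletion without replicates 2 and 3.

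**Figure D2:**
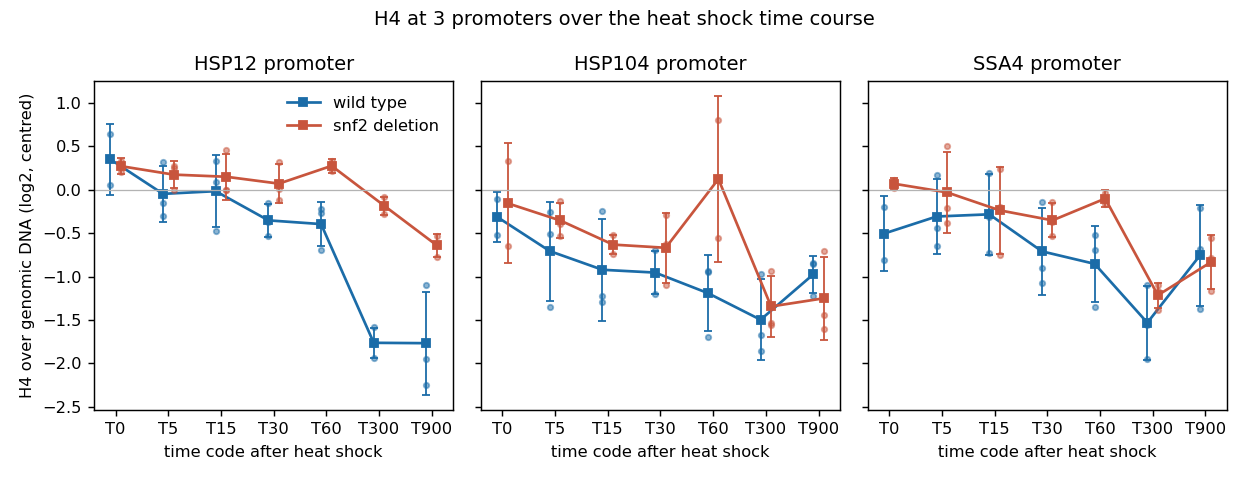
H4 over genomic DNA (log2) at the HSP12, HSP104 and SSA4 promoters by time code, equally spaced, in wild-type and snf2 deletion cells, with points for arrays, squares for means and bars for the SD. At T300 HSP12 was at -1.76 in wild type and -0.18 in the deletion, while HSP104 was at -1.50 and -1.34.

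Acetylated H4 over genomic DNA during the same time course was higher in the snf2 deletion at stress gene promoters. Of the 276 probes with higher H4 in the deletion, 188 also had higher acetylated H4, against 24.1 expected. Acetylated H4 was not set against H4 in this course, so more H4 and more acetylation cannot be told apart at such probes. Averaged over times it lay higher at the promoters of SED1 (1.72), of the glycogen synthase gene GSY2 (1.68) and of HSP82 with YAR1 (1.19). The same held for the promoters of CTT1 with PDC6 (1.10), of HSP104 (1.08), of SSA4 (0.92, adjusted p = 2.91e-09) and of HSP12 (0.69), and at an intergenic probe beside YDR077W (2.19, SE 0.14, adjusted p = 3.57e-13). It was lower at SNF2 (-1.35) and at the promoter of RPL19A with AAC3 (-0.74). With 1 value per set the adjusted p was 0.00127 beside YDR077W, 0.00101 for SED1, 0.00164 for GSY2, 0.00298 for HSP82, 0.00576 for CTT1 and HSP104, 0.00290 for SSA4 and 0.00143 for SNF2. The HSP12 (0.0810) and RPL19A (0.0708) promoters did not pass on set values. General stress promoters were higher in 19 of 23 cases (20 adjusted over the list alone), with a median of 0.69 and adjusted p = 0.00419 with an estimated correlation. Chaperone promoters were higher in 18 of 29 (23 adjusted over the list alone), with a median of 0.53 and adjusted p = 0.00419 with an estimated correlation. The list tests take the repeated times of a set as independent arrays and were not repeated with 1 value per set. At the CTT1 promoter the wild type went from 0.14 (n = 2) at T0 to -1.44 ± 0.21 (SD, n = 3) at T900, and the deletion from 0.96 to 0.89 ± 0.09 (n = 2). The T900 difference between these changes was 1.51 (unadjusted p = 0.00319 in limma, adjusted p = 1.0), and the adjusted p over all times was 0.127. The time response differed between strains past the threshold at the aromatic aminotransferase gene ARO9 (F = 10.8, adjusted p = 0.0245), an intergenic probe beside YOL053W (F = 9.99, adjusted p = 0.0259) and HSP42 (F = 9.27, adjusted p = 0.0348). In wild type at T900 acetylated H4 rose at the polyamine exporter gene TPO2 (1.32, SE 0.26) and HIS4 (1.14, SE 0.21) and fell at the CTT1 promoter (-1.58, adjusted p = 0.0402) and TPS1 (-1.18). In the deletion it fell at HSP42 (-2.55, SE 0.35, adjusted p = 0.000534), at TPS1 (-1.64) and at the glycolytic gene PGK1 (-1.61).

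The strain difference of acetylated H4 was called at 1556 probes, 1136 higher and 420 lower in the deletion. With set numbers as a replicate block it was 2396 (1559 higher, 837 lower), and without centring the split was 1056 higher and 904 lower. With 1 value per set it was 465 (426 higher, 39 lower). Over promoters of heat-induced genes that rose at least 2-fold the difference was 0.14, 0.30 and 0.20 in sets 1, 2 and 3, positive at 7 of 7 time codes (exact p of 0.25 by exchanging whole sets, the smallest that 8 exchanges allow). Without replicates 2 and 3 in turn it was 380 and 836. In set 1 alone, in which both strains share wild-type genomic DNA as reference, it was 68 (65 higher, 3 lower). Per the labels, sets 2 and 3 of the deletion used genomic DNA of the deletion strain, and the SNF2 ORF probe averaged -1.54, -2.33 and -2.76 in deletion sets 1, 2 and 3 and -0.46, -1.10 and -1.24 in those of wild type. The wild-type T900 test called 8 probes, 4 in each direction (123 with the block, 21 higher and 12 lower with the arrays scaled), and 1, 1 and 0 without replicates 1, 2 and 3. The deletion's called 12, 1 higher and 11 lower (50 with the block), and 4 and 22 without replicates 2 and 3. The test of a strain difference in the time response called 3 (9 with the block, 8 higher and 2 lower in mean without centring), and 1 and 0 without replicates 2 and 3. Tests over all times called 65 probes in wild type and 65 in the deletion (234 and 193 with the block). They gave 0 and 1 in wild type without replicates 2 and 3, and 43, 4 and 18 in the deletion without replicates 1, 2 and 3.

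Expression over the heat shock time course, measured on poly(A) RNA at 0, 30, 60, 300 and 900 s, set the response of wild-type cells beside that of arrays labelled snf2 deletion. The SNF2 probe did not show a clear loss on the arrays labelled snf2 deletion, at -0.05 and -0.03 at 0 s against 0.32 and 0.67 in wild type, and its own fall did not pass the test. In wild type at 900 s the hexose transporter gene HXT5 rose by 4.64 (SE 0.19, adjusted p = 3.87e-05), BTN2 by 4.39 (SE 0.18), NQM1 by 4.29 (SE 0.25) and HSP30 by 4.16 (SE 0.17). URA1 (-4.15, SE 0.18), RPS0A (-3.85, SE 0.16) and the nucleolar gene NSR1 (-3.76, SE 0.15) fell. On the arrays labelled snf2 deletion HSP30 rose by 4.72 (SE 0.20, adjusted p = 0.000569), SPI1 by 4.55, HSP12 by 3.93 and HSP42 by 3.59, and ARO4 (-2.81) and the glutamate dehydrogenase gene GDH1 (-2.80) fell. The limma test of a strain difference at 900 s, where the snf2 label has 1 array whose spread was borrowed from the other groups, called 17 genes, 11 with a lower and 6 with a higher change on that array, and 0 when any 1 of the 4 arrays at 0 s was left out. HXT5 rose by 4.64 in wild type and was at 0.95 on the arrays labelled snf2 deletion (difference -3.68, SE 0.31, adjusted p = 0.0171). ALD3 was at 4.03 and 0.44 (difference -3.59), the alcohol dehydrogenase family gene BDH2 at 2.95 and 0.02 (difference -2.93). NSR1 was at -3.76 and -1.58 (difference 2.19) and the siderophore transporter gene SIT1 at -1.81 and 2.47 (difference 4.28). CTT1 had a difference of -2.97 (adjusted p = 0.119) and HSP12 of 0.51 (adjusted p = 0.585), and neither passed.

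General stress genes rose in 25 of 30 cases in wild type at 900 s (25 and 1 fall adjusted over the list alone), with a median change of 2.29 (adjusted p = 0.0900 with an estimated correlation). They rose in 16 of 30 on the arrays labelled snf2 deletion (18 adjusted over the list alone), with a median of 1.27 (adjusted p = 0.123 with an estimated correlation). The difference between strains in this list had a median of -0.51, with 3 genes past the threshold (7 adjusted over the list alone; adjusted p = 0.325 with an estimated correlation). Chaperone genes rose in 28 of 30 cases in wild type and 24 of 30 on the arrays labelled snf2 deletion (28 and 27 adjusted over the list alone), with medians of 2.51 and 1.77 (adjusted p = 0.0900 and p = 0.123 with an estimated correlation). Ribosomal protein genes fell in 130 and 113 of 136 cases (132 and 128 adjusted over the list alone), with medians of -2.83 and -1.82 (adjusted p = 0.144 and p = 0.148 with an estimated correlation). Before heat shock the arrays labelled snf2 deletion had more DAL80 mRNA, a repressor of nitrogen catabolism (2.23, SE 0.18, adjusted p = 0.00240). They had less YRO2 (-4.17, SE 0.19), YGP1 (-3.27, SE 0.19), TIP1 (-3.20, SE 0.20) and the acid phosphatase gene PHO3 (-2.91, SE 0.18). Of 17 glycolytic genes 8 were lower (11 adjusted over the list alone; adjusted p = 0.456 with an estimated correlation). The tests called 1637 genes in wild type at 900 s (649 higher, 988 lower), 622 on the arrays labelled snf2 deletion (241 higher, 381 lower) and 397 between strains at 0 s (120 higher, 277 lower). Without wild-type 0 s replicates 1 and 2 in turn the wild-type count was 819 and 847 and the count between strains at 0 s 4 and 16. The count labelled snf2 deletion was 286 each, and the 17 became 0 each, in the same order. Without the snf2 0 s replicates 1 and 2 these were 173 and 83 at 0 s, 292 and 396 on the arrays labelled snf2 deletion and 0 each for the 17, which was 60 and 45 without wild-type 900 s replicates 1 and 2. Times and strains with 1 array were assumed to vary like the others.

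**Figure D3:**
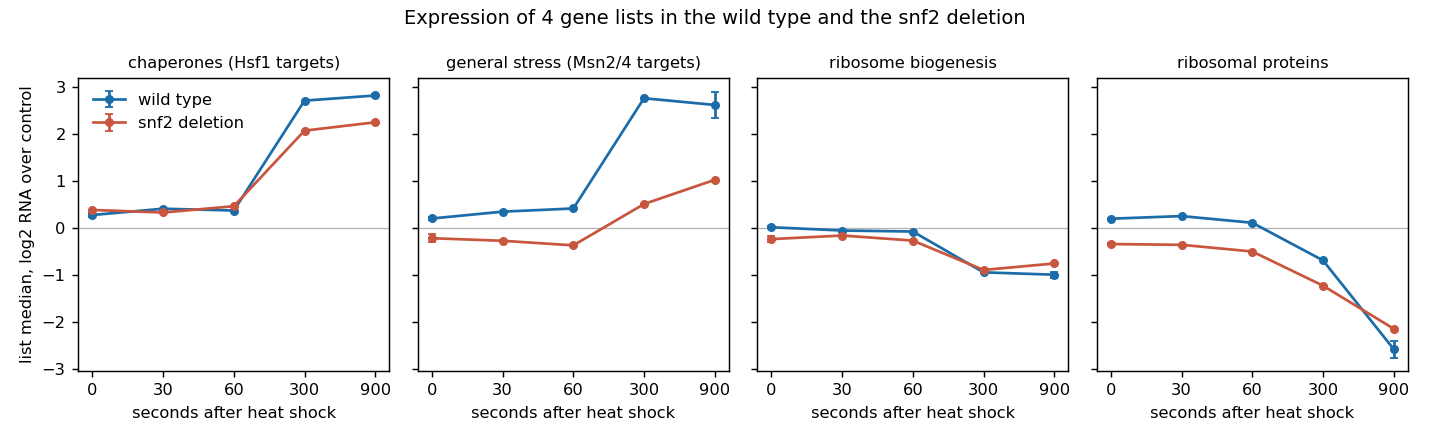
Median log2 expression of chaperone, general stress, ribosome biogenesis and ribosomal protein genes relative to control RNA at 0, 30, 60, 300 and 900 s of heat shock, equally spaced, in wild type and on arrays labelled snf2 deletion, with bars from the lowest to the highest array where there were 2 arrays. At 300 s the general stress median was 2.75 in wild type and 0.50 on arrays labelled snf2 deletion, and at 900 s 2.61 and 1.02.

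Single arrays, without replicates, compared total RNA of strains labelled as deleted for SNF2, or for CHD1, ISW1 or ISW2, which encode other chromatin remodelling ATPases, with wild type and across heat shock. The titles of 4 of the arrays against wild type name no temperature, and 30°C was taken for them. The deleted gene's probe was low for ISW1 (-2.45 at 30°C, -2.09 at 39°C), ISW2 (-2.04 and -1.71) and CHD1 at 30°C (-2.89), with SNF2 at -1.34 at 39°C. A loss was not clear for CHD1 at 39°C (-0.44) or for SNF2 at 30°C (-0.40, against -0.29 and -0.23 on the arrays labelled chd1 and isw1 deletion). At 30°C the array labelled snf2 deletion had more HSP12 mRNA than wild type (4.64), as had those labelled chd1 (3.18), isw1 (4.42) and isw2 deletion (2.60), whereas on the time course arrays at 0 s HSP12 was lower under the snf2 label (-1.96, adjusted p = 0.00622). General stress mRNA was higher on all 4 single arrays against wild type at 30°C, with list medians of 1.48, 1.46, 1.37 and 0.84 and 20, 20, 20 and 13 of 30 genes at least 2-fold higher in the same order. On these arrays the actin gene ACT1 was at 0.34, 1.76, 1.47 and 1.21. A rise was thus not confined to stress genes under the chd1, isw1 and isw2 labels. Whether the wild-type RNA deviated was not tested. On the time course arrays labelled snf2 deletion, before heat shock, 7 of 30 general stress genes were lower (10 adjusted over the list alone), with a list median of -0.20 (adjusted p = 0.456 with an estimated correlation). In wild type the single heat shock array had ribosomal protein mRNA at -3.09 (list median), chaperone mRNA at 2.47 and general stress mRNA at 2.12. On the array labelled snf2 deletion these were -1.38, 2.05 and 1.10, and ribosome biogenesis mRNA was at -0.12 against -1.29 in wild type. Among the 436 genes repressed at least 2-fold on the replicated heat shock arrays, the median was -1.97 in wild type and -0.57 on the array labelled snf2 deletion, and among the 373 induced it was 1.06 and 0.88. At 39°C the array labelled snf2 deletion, set directly against wild type, had more ribosomal protein mRNA (median 1.02, RPS9B at 2.09) and less iron regulon mRNA (median -0.93, FET3 at -2.84, SIT1 at -2.12). On the time course arrays SIT1 rose from 0 s to the last time under the snf2 label (2.47) and fell in wild type (-1.81). The strain difference in that response (4.28) had the opposite sign to SIT1 on the 39°C array, and the cause was not tested. With 1 array each the differences on the single arrays were not tested. On the 30°C arrays the median of the ORF probes after centring lay 0.12 to 0.26 above 0.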

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

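The tests of the stationary-phase pattern below were chosen only after the result was seen, as were the slope at the probes changed at least 2-fold, the splits that keep pairs or whole sets, the fits with 1 value per set, the values of acetylated H4 in set 1 alone and those with the Snf2 print batches.

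A limma test of the difference between wild type and the arrays labelled snf2 deletion in the response to 900 s of heat shock called 17 genes over 13 arrays. That label has 1 array at 900 s, so any deviation of that array enters the difference, its spread was borrowed from the other groups, and on simulated data the test recovered 0% of changes of 2. The differences, arrays labelled snf2 deletion minus wild type, had adjusted p between 0.0171 and 0.0495. The negative ones were HXT5 (-3.68), ALD3 (-3.59), YBR116C (-2.97), BDH2 (-2.93), RTN2 (-2.81), GND2 (-2.49), TSA2 (-2.31), DIP5 (-2.17), FMP45 (-2.13), PCL5 (-2.05) and DSE4 (-1.94). HXT5 transports hexoses, TSA2 is a peroxiredoxin and DIP5 takes up amino acids. The positive ones were YLR334C (1.96), NSR1 (2.19), ADR1 (2.73), SMC3 (2.76), SPR28 (3.56) and SIT1 (4.28), of which ADR1 encodes an activator of glucose-repressed genes and SMC3 a cohesin subunit. Without either wild-type 0 s array or either snf2 0 s array the count of 17 became 0, and without wild-type 900 s replicates 1 and 2 it was 60 and 45. The time response of acetylated H4 differed between the strains at 3 probes, ARO9, an intergenic probe beside YOL053W and HSP42, by the same kind of test (F = 10.8, 9.99 and 9.27), and at 1 and 0 without replicates 2 and 3.

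The direct arrays of heat-shocked against unstressed chromatin called 2808 probes for H4, and the ratios to genomic DNA called 40. The median standard error was 0.148 for the ratios to genomic DNA against 0.0633 for the direct arrays, a ratio of 2.34, so a wider spread between arrays may account for the lower count. A gene-specific dye effect stays open for the called probes as a whole: the change through genomic DNA, in which the dye cancels, had a slope of 0.46 on the direct change, between the values that would have decided it, and the same sign in 76.1%. Choosing probes by their values on the direct arrays lowers this slope by itself. A low slope therefore need not come from a dye effect, here or at the 2-fold changes below. At the 74 probes that changed at least 2-fold the slope was 0.62 (0.52 to 0.80 in the 3 sets) and the sign the same in 97.3%, so part of these changes was seen without the dye, while the slope did not exceed the deciding value of 0.5 by more than the SD of the sets (0.16). The falls at the HSP82, BTN2 and HSP104 ORFs and the SSA4 promoter also passed the threshold through genomic DNA (adjusted p = 0.000555, 0.00377, 0.0231 and 0.0237).

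Acetylated H4 was higher in the snf2 deletion over the time course at 1136 probes and lower at 420. The same profile with another amplitude is argued against, since the strain difference had r = -0.15 with the wild-type profile across probes. The genomic DNA of the deletion strain, the reference of sets 2 and 3 per the labels, may account for a part if it was used. In set 1, where both strains share wild-type DNA, the median difference was 0.469 of that in sets 2 and 3. The medians were 0.19 and 0.41 over 1973 probes called from sets 2 and 3. With 1 set on one side the reference and the spread between sets cannot be told apart. Choosing probes by their calls in sets 2 and 3 also lowers that share by itself, without any effect of the reference. The sign in set 1 was the same at 79.3% of those probes. The SNF2 ORF probe argues against the labelled reference, under which both channels of these deletion arrays would lack SNF2. In sets 2 and 3 it was at -2.33 ± 0.67 and -2.76 ± 0.22 in the deletion (SD, n = 7 arrays each). In wild type it was at -1.10 ± 0.18 and -1.24 ± 0.24, and in set 1 at -1.54 in the deletion and -0.46 in wild type. Only this probe was checked. The strains themselves, which the design names, stay among the open explanations.

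On the direct stationary-phase arrays 722 probes lost at least 2-fold of acetylated H4, with a median of -1.22, while the ratios to genomic DNA gave a median of 0.19 at these probes. A gene-specific dye effect is argued against, since acetylated H4 per H4, a difference of ratios in which the dye cancels, showed 1.01 times the fall (median -1.23). Total H4 in the precipitate in place of acetylated H4 was tested by correlation: the direct change had r = 0.866 across probes with the change of H4 plus that of acetylated H4 per H4 and 0.598 with the direct H4 change, a difference of 0.268. That result goes against total H4. However, acetylated H4 per H4 also had falls at ORF probes that the probes beside them did not share. Such a shared probe effect can raise the first correlation, so what was precipitated is not decided. A candidate explanation is the position of the ORF probes on the print, for which probe names served in place of print positions. The 595 intergenic probes beside the fallen ORFs had a median of 0.02, a share of -0.0193 of the fall, which goes with it. Of the ORF probes named YPR 36.1% fell and of those named YOR 16.9%, against 6.2% of all. These names held 73 and 68 of the 388 fallen ORF probes, so most of the fallen ORF probes had other names. Print position does not by itself account for the median of 0.19 through genomic DNA, so it stays open. No biological explanation was tested.

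Other divisions of the same arrays were counted for each comparison of groups. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave the most calls, as 1 of 10, for H4 (40 probes, highest other 10) and acetylated H4 (643, highest other 0) through genomic DNA after heat shock. The same held for their ratio after heat shock (8, highest other 0) and for the ratio in stationary phase (640, highest other 0). Through genomic DNA in stationary phase limma called 0 probes for both, with 1469 for H4 and 2342 for acetylated H4 at unadjusted p under 0.05, so 10 of 10 splits gave as many (highest other 1 and 0). For the Snf2 change 2 of 56 splits gave 8 or more with the arrays taken as independent, and the highest other gave 601, which points to a structure of the samples. With the print batches as a block the change gave 2 calls, so these splits do not exclude chance. That split set heat sets 2, 3, 4 and 5 with 30°C set 3 against 30°C sets 1 and 2 with heat set 1. For the strain difference 2 of 100 splits gave as many probes for H4 (306, highest other 592) and 2 of 100 for acetylated H4 (1556, highest other 2883). Among splits that keep the pairs of set numbers, 1 of 100 gave as many for each, with highest others of 6 and 283. Both kinds of split exchange single arrays, whereas the arrays of 1 set and strain are repeated times that correlate (r up to 0.63 for H4 and 0.69 for acetylated H4). Exchanging the strains of whole sets leaves 4 arrangements, too few for a share under 0.05, with a highest other of 96 for acetylated H4. With 1 value per set and the strains paired, limma called 117 probes for H4 and 465 for acetylated H4. For the strain difference in the time response of H4 limma called 0 probes (119 at unadjusted p under 0.05), so 100 of 100 splits gave as many by construction (highest other 243) and the count decides nothing. For acetylated H4 (3 probes) 2 of 100 splits gave as many (highest other 27), but 8 of 100 of those that keep the pairs did (highest other 296), so chance is not excluded.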

How the results depend on the processing

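Alternatives chosen only after the result was seen are centring on the ORF probes, the Snf2 print batches, set 1 alone, 1 value per set and the H4 count without ribosomal DNA. Over 42 results and 320 values under alternatives, 188 kept their direction and stayed within 1.5 times the count or on the same side of the threshold and 132 changed. Complete probes changed 0 of 31 values, promoters serving 1 gene 0 of 7, robust eBayes 1 of 31, values without centring 9 of 35, scaled arrays 12 of 31 and leaving out a replicate 74 of 132. Of 6577 values at 755 named probes 5990 stayed on the same side, 509 fell short of the threshold, 64 newly passed it and 14 reversed. Among 750 list tests 164 fell short of the threshold with an estimated correlation and 586 stayed. Most of the 586 had no call under either setting, and nearly every list call was lost. Calls remained only in the time courses, whose repeated times were taken as independent. These were 1 of 7 lists for H4 in wild type at T900, 1 of 6 for the H4 strain difference and 5 of 8 for that of acetylated H4. In each group the number of arrays sets the limit, background intensities are not analysed here, and the cause was not tested for any of the values that follow unless stated.

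Without centring the counts were 173 for Snf2 before heat shock and 0 for its change, and 17 and 394 for acetylated H4 per H4 after heat shock and in stationary phase. They were 43 and 125 for acetylated H4 in wild type at T900 and over all times, 21 and 115 in the snf2 deletion, and 10 for strain by time. The H4 split after heat shock became 63.6% higher from 46.6%.

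With the arrays scaled the counts were 150 for H4 through genomic DNA after heat shock, 14 for H4 in the deletion over all times, and 1324 for Snf2 before heat shock and 23 for its change. They were 23 and 0 for acetylated H4 per H4 after heat shock and in stationary phase, 33 and 113 for acetylated H4 in wild type at T900 and over all times, and 3 and 35 in the deletion. They were 206 for expression on the arrays labelled snf2 deletion and 2 for the expression difference between strains. Robust eBayes gave 19 for acetylated H4 per H4 after heat shock.

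With the set number as a replicate block the counts were 8 for H4 through genomic DNA after heat shock, 24 for acetylated H4 per H4 after heat shock and 0 for the Snf2 change. For H4 in the time course they were 20 in wild type at T900 and 131 over all times, 11 and 35 in the deletion and 570 for the strain difference. For acetylated H4 they were 123 and 234 in wild type, 50 and 193 in the deletion, 2396 for the strain difference and 9 for strain by time. The Snf2 change gave 2 with the print batch as a block and 0 in the larger batch alone, which has fewer arrays. Set 1 alone, also with fewer arrays, gave 68 for the strain difference of acetylated H4, with MDM36 at 0.30 in place of a fall. With 1 value per set, which leaves 3 values per probe, the strain difference gave 117 for H4 and 465 for acetylated H4. H4 in stationary phase gave 238 without ribosomal DNA, mitochondrial probes and ORFs beside the ribosomal DNA, since those probes were removed.

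As differences of the ratios to genomic DNA, the direct counts became 40 for H4 and 643 for acetylated H4 after heat shock and 0 for both in stationary phase (limma, 1469 and 2342 at unadjusted p under 0.05). Reversed were H4 after heat shock at GIM3 (-0.55) and the HSP26 promoter (0.0389) and acetylated H4 after heat shock at the HSP42 promoter (0.14). In reverse were also H4 in stationary phase at CPT1 (0.24), CRC1 (0.15), ELG1 (0.15), SSS1 (0.13) and YPR196W (0.27). The same held for acetylated H4 in stationary phase at CEN4 (0.20), DPB2 (0.55), LEU9 (0.80), RPT5 (0.52) and SFL1 (0.61). With centring on the ORF probes the general stress list on the array labelled snf2 deletion against wild type at 39°C moved to -0.38.

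At promoters of responsive genes, taking only genes with at least a 2-fold change gave, for induced genes after heat shock, -0.19 for H4, 0.29 for Snf2, and 0.0593 for acetylated H4 per H4. It reversed acetylated H4 directly (-0.0926) and through genomic DNA (-0.13). In stationary phase acetylated H4 per H4 at induced genes was 0.21. Over ORF probes of the same genes the values after heat shock were -0.0577 for H4, and reversed at -0.0206 for acetylated H4, -0.0622 for it through genomic DNA and -0.0044 per H4, all for induced genes. In stationary phase induced genes gave 0.0079 for H4 (reversed), 0.0476 for acetylated H4, -0.0738 for it through genomic DNA (reversed) and 0.13 per H4. Repressed genes gave 0.0846, 0.0724 and 0.0458 for acetylated H4 directly, through genomic DNA and per H4, all reversed.

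Leaving out 1 replicate in turn, which leaves fewer arrays, gave 1311 to 2569 for expression after heat shock and 1284 to 2158 in stationary phase. It gave 961 to 4310 for H4 and 1997 to 4564 for acetylated H4 after heat shock, and 0 to 331 for H4 and 678 to 1340 for acetylated H4 in stationary phase. Through genomic DNA after heat shock H4 gave 0 to 361 and acetylated H4 50 to 805, and acetylated H4 per H4 gave 0 to 0 under both stresses. Snf2 gave 0 to 2896 before and 1218 to 2875 after heat shock and 0 to 0 for the change. The H4 time course gave 0 to 6 in wild type and 3 to 5 in the deletion at T900, 3 to 15 and 0 to 6 over all times, and 86 to 249 for the strain difference. Acetylated H4 gave 0 to 1 and 4 to 22 at T900, 0 to 70 and 4 to 43 over all times, 0 to 2 for strain by time and 380 to 1973 for the strain difference. Expression in the time course gave 819 to 1705 in wild type, 286 to 874 on the arrays labelled snf2 deletion, 4 to 577 between strains at 0 s and 0 to 60 for the difference in response.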

Other observations

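The test of H4 at probes with Snf2 was chosen before its result was seen.

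Genes of mating type moved apart under the stresses. After heat shock 6 of 13 rose and 5 fell, the same counts adjusted over the list alone. The list median was 0.27 and its mean -0.20, so the 2 differ in sign, with the a-factor receptor gene STE3 at -2.49 and the alpha-factor genes MF(ALPHA)2 at -2.12 and MF(ALPHA)1 at -1.94. In stationary phase 5 rose and 4 fell, again the same adjusted over the list alone, with the alpha-factor receptor gene STE2 at 2.02, the agglutinin subunit AGA2 at 1.88 and the a-factor gene MFA1 at 1.78, all log2 changes over 3 arrays. Hexose transporters after heat shock rose in 6 of 18 cases and fell in 2 (6 and 3 adjusted over the list alone), with HXT5 at 2.35, the glucose sensor gene SNF3 at 1.64 and HXT3 at -0.96. In stationary phase HXT5 was at 3.19 and HXT2 at -1.69. Of 22 ergosterol biosynthesis genes 9 fell after heat shock (11 falls and 1 rise adjusted over the list alone), with a median of -0.40 and ERG13, which encodes HMG-CoA synthase, at -1.58. Proteasome genes rose after heat shock in 8 of 31 cases (8 adjusted over the list alone), with a median of 0.35, SCL1 at 0.97 and RPN11 at 0.81, and the list did not pass (adjusted p = 0.0600 with the preset correlation).

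Core histone genes fell in 4 of 10 cases in stationary phase (5 falls and 1 rise adjusted over the list alone), with the H2B gene HTB2 at -0.92, the H4 genes HHF1 at -0.75 and HHF2 at -0.60, and the H2A.Z gene HTZ1 at -0.59. After heat shock 2 rose and 2 fell (2 and 3 adjusted over the list alone), with a median of -0.20. SWI/SNF subunit genes fell after heat shock in 3 of 12 cases (2 adjusted over the list alone), with a median of -0.18, TAF14 at -0.65, SWI3 at -0.57 and ARP7 at -0.46. Genes known to depend on SWI/SNF went both ways: after heat shock 5 of 22 rose and 2 fell, the same adjusted over the list alone, with the invertase gene SUC2 at 1.07 and the acid phosphatase gene PHO5 at -1.50. In stationary phase 5 of them rose and 5 fell, the same adjusted over the list alone, with the inositol gene INO1 at 2.67 and the alcohol dehydrogenase gene ADH2 at -1.98. None of the lists in this paragraph and the one before passed the camera test with the preset correlation.

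H4 may lie higher in the snf2 deletion where Snf2 was found in wild type. Over 2149 probes above input for Snf2 before or after heat shock against 10871 others, the median strain difference was 0.0536 higher. The sets gave 0.0550, 0.0740 and 0.0426. The value of 0.0536 lies between the 0.1 that would have spoken for the hypothesis and the 0.05 that would have spoken against it. Of the 276 probes called higher for H4 in the deletion, 174 were above input for Snf2 after heat shock, against 39.8 expected. Before heat shock 30 of them were, against 14.2 expected. These counts go with the hypothesis at the called probes, and over all probes with Snf2 it is left open.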
